A study of Mus musculus with 48 samples.

How the data were processed

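Messenger RNA of mouse cardiomyocytes was measured by RNA sequencing in 48 libraries. Per the labels' protocols, cells were isolated by collagenase perfusion after removal of the right ventricle and the atria, and libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument. The extract protocol in the labels describes mapping with the sequencing provider's own algorithm, while the submitters' processing notes name CASAVA 1.8.2, Bowtie, RSEM 1.2.0 and the mouse build mm9. Which of these made the table is not settled by the labels. The deposited file holds RSEM expected counts per gene symbol, not normalized by the authors, with 30743 rows and 1 column per library, and 13.9% of the values were not whole numbers. The file held 0 columns of other samples and 0 rows that name no gene. Gene symbols were used as the file gives them, and no coordinates are given because the reference at hand was of another build. RSEM divides reads shared by near-identical genes among them, so values of such copies, the nuclear and mitochondrial copies of mitochondrial genes included, are uncertain.

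Groups were taken from the labels: the genotype tag, the treatment label and the title. The replicate numbers named each library and none was shared between groups, so no pairing was used. Whether libraries of a group came from separate animals is not stated apart from these numbers, so p-values measure the spread between these libraries. Libraries of a group were compared pairwise: the lowest chi-square per degree of freedom was 3.858, so no pair appeared to be 1 library under different names. Xist had 0 to 2 counts in every library, so sex was not used as a covariate.

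Expected counts were rounded to whole numbers and analysed in R 4.3.3. The test was edgeR 4.0.16's quasi-likelihood F test with TMM normalization, edgeR's filter on low counts by group, Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The ACF comparisons used the 24 libraries of set A in 1 model of group means (13440 genes), as differences within each labelled genotype, their mean, and the differences between them. The sham comparisons used 36 libraries with the set as a covariate (13276 genes), and the same comparisons were fitted within set A and within set B (13395 genes). Levels are log2 CPM with a prior count of 2. Libraries held 15.89 to 26.09 M counts.

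Gene lists, 33 in number, covered metabolic, contractile, stress, signalling and matrix genes and markers of other cell types. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. List p-values were adjusted over the lists measured in a comparison. For the list of 13 mitochondrially encoded proteins 2 symbols matched, Cytb and Cox2, and Atpase6 was added after the file was seen. The count adjusted over the list alone is given beside that over all genes.

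The tests, groups, gene lists, named-gene rule and the other settings below were fixed before the data were examined. The rule named, for the mean ACF effect and for the nuclear comparison, up to 12 genes per direction with the largest log2 fold change among those past the threshold with a mean log2 CPM of at least 3 and 1 sign in every genotype (or in both sets and both mitochondrial backgrounds). For the other comparisons it named up to 5 per direction with a mean log2 CPM of at least 2. It skipped predicted, clone and pseudogene symbols, added up to 4 members of a called list, and always named Nnt, Nppa, Nppb, Myh6, Myh7, Acta1 and the mitochondrially encoded genes. Some genes that the rule names are not reported here. These settings were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, leaving out each library in turn, other choices of sham libraries or of libraries in the fit, each set alone, no set term, and, as a covariate, a code of L and a digit in the titles whose meaning the labels do not state. Chosen after seeing the data were the strain score, the reading of the title prefix as nuclear background, the fits without library 489 as a second set of named genes and without libraries 489 and 6756, the use of the named-gene rule within set B alone, and within set B alone the fits under the other settings, the L code as a covariate and each library left out in turn among them.

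The strain score used genes for which every C3Hn library of set B lay on one side of every C57n library by over 1.5 on the log2 scale, with a mean log2 CPM of at least 1 (58 higher in C3Hn and 33 higher in C57n). Since set B defined these genes, the score says how set A compares with set B and does not check the labels of set B. For that check, also chosen after seeing the data, the genes were chosen on C3Hn:C3Hmt and C57n:C57mt of set B alone (68 higher in C3Hn and 40 higher in C57n) and read in the exchanged libraries. The difference in Nnt was tested with 100000 permutations. The fits were tested on simulated counts with 200 changed genes at the real means, spreads and library sizes. The changed genes were drawn from those with a mean log2 CPM above 1, so the recovered shares do not cover genes below that level. Each simulated gene was drawn independently of the others. For the mean ACF effect over 13440 genes 71.6% of genes changed 1.5-fold, 94% at 2-fold and 100% at 4-fold were recovered, with 13 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.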

Results

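RNA from mouse cardiomyocytes was sequenced in 48 libraries from mitochondrial-nuclear exchange mice, in which the nuclear genome of one inbred strain is combined with the mitochondrial genome of another. The strains were C57BL/6J (C57) and C3H/HeN (C3H), and the 4 genotypes are written as nuclear and mitochondrial background, so that C57n:C3Hmt is a C57 nucleus with C3H mitochondria. The unexchanged C57n:C57mt and C3Hn:C3Hmt were the wild-type strains. Animals had sham surgery or ACF. ACF was the surgery of a volume overload study (the abbreviation commonly stands for aortocaval fistula). Cells were taken on day 3. In 24 libraries the titles carried the surgery, with 3 sham and 3 ACF libraries per genotype (set A). The titles of the other 24 carried no surgery word, and their treatment label was sham, with 6 libraries per genotype (set B). Total counts ran from 15.89 to 20.77 M (mega) per library in set A and from 15.97 to 26.09 M in set B, over 30743 gene rows. The 6 most abundant features, among them the mitochondrial transcripts Cytb, Atpase6 and Cox2, took 40.02% to 64% of the counts of a set A library and 18.05% to 53.45% of those of a set B library. The ribosomal RNA precursor Rn45s had a log2 CPM of 7.83 to 9.68 in set A and of 10.71 to 12.41 in set B, so the sets did not overlap in it.

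The genotype labels were examined first. Kcnj14, a potassium channel gene, had a mean log2 CPM of 6.63 ± 0.201 (SD, n = 6) in C3Hn:C57mt of set B and 0.97 ± 0.156 (SD, n = 6) in C57n:C3Hmt of set B. In set A the order was the opposite, with -1.38 ± 0.706 (SD, n = 3) in the sham libraries labelled C3Hn:C57mt and 5.83 ± 0.263 (SD, n = 3) in those labelled C57n:C3Hmt. The 58 genes that set the C3Hn libraries of set B above its C57n libraries, by a gap of over 1.5 on the log2 scale, gave each library a score, the median over these genes, of 0 at the C57n mean and 1 at the C3Hn mean. In set A the libraries labelled C57n:C3Hmt scored 0.928 to 0.949 (sham) and 0.866 to 0.99 (ACF). Those labelled C3Hn:C57mt scored -0.0149 to -0.014 (sham) and -0.0117 to 0.0129 (ACF). All 12 set A libraries with an exchanged genotype label therefore had the nuclear expression profile opposite to the label. Their titles begin with the strain that the profile matched. The set A libraries labelled C3Hn:C3Hmt and C57n:C57mt scored on the side of their label. With 68 genes chosen in the same way on the unexchanged set B libraries alone, the exchanged set B libraries scored 0.99 to 1.02 (C3Hn:C57mt) and 0 to 0.0388 (C57n:C3Hmt), on the side of their nuclear label. Whether the mitochondrial label of those 12 libraries is right could not be tested from gene counts. They are called by their labels here and every direction drawn from them carries that doubt.

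**Figure D1:**
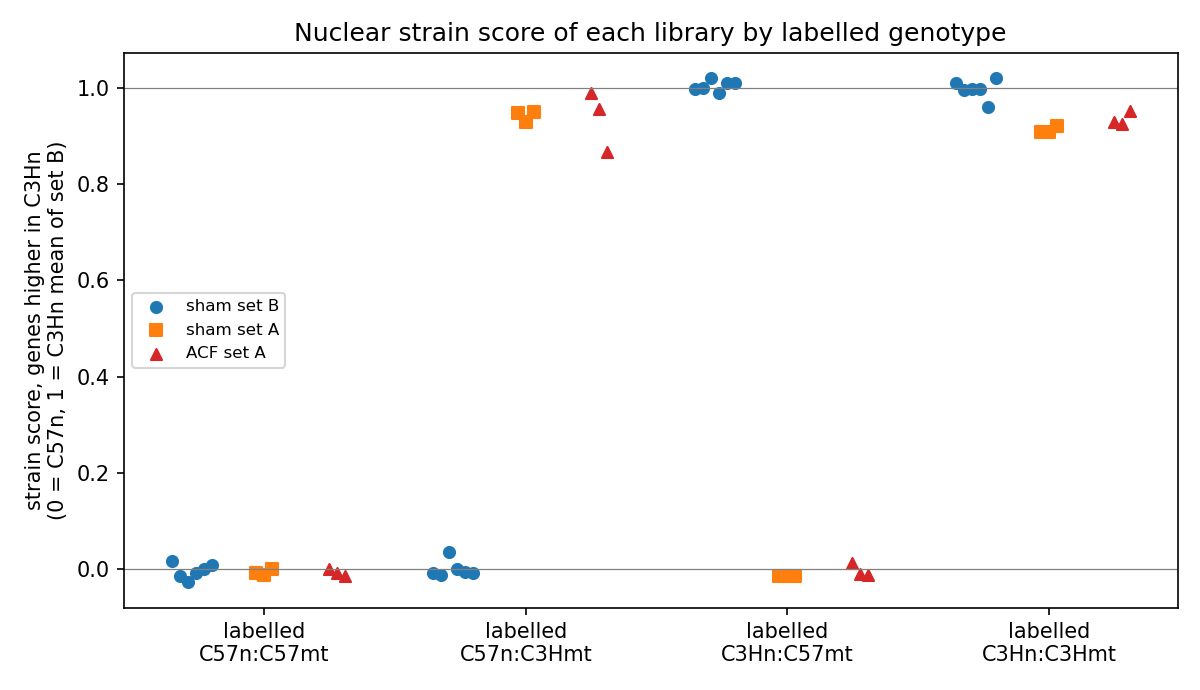
Strain score per library (0 is the C57n mean and 1 the C3Hn mean of set B) from the 58 genes higher in C3Hn, by labelled genotype, surgery and set; each point is 1 library. The 12 set A libraries with exchanged labels lie on the side opposite to the labelled nucleus, at 0.866 to 0.99 and at -0.0149 to 0.0129.

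Nnt, the nicotinamide nucleotide transhydrogenase gene of which C57BL/6J carries an internal deletion, had been chosen as a label check. Its mean log2 CPM in set B was 9.02 ± 0.281 (SD, n = 12) in C3Hn and 8.74 ± 0.154 (SD, n = 12) in C57n libraries, a difference of 0.28 (2-sided permutation test, p = 0.006). The test pooled the mitochondrial backgrounds, and most of the difference lay with C57 mitochondria. There Nnt had 9.17 ± 0.192 in C3Hn and 8.65 ± 0.152 in C57n libraries. With C3H mitochondria it had 8.86 ± 0.282 and 8.82 ± 0.107 (SD, n = 6 each). Between the set A libraries as labelled, Nnt had 8.85 ± 0.291 in C3Hn and 8.54 ± 1.01 in C57n (SD, n = 12 each; permutation p = 0.4). An ACF library of C57n:C57mt, library 489, had the lowest Nnt value (5.40), and without it C57n had 8.82 ± 0.211 (SD, n = 11), a difference of 0.03 (permutation p = 0.75). The counts are per gene, and the deleted exons were not examined.

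Library 489 stood apart in transcripts of other cells. The erythrocyte genes averaged a log2 CPM of 11.84 in it against -1.33 to 4.88 in the other set A libraries. The haemoglobin gene Hba-a2 was at 15.99 and Alas2, the erythroid haem synthesis gene, at 12.04. Macrophage genes averaged 4.64 against 1.29 to 3.45, and neutrophil genes 3.92 against -2.18 to 2.62. Lymphocyte genes averaged 2.32 against -2.36 to -0.41, and fibroblast genes 6.68 against 3.67 to 6.19. Cardiomyocyte genes averaged 8.79 in library 489 and 10.97 to 12 in the others. Library 6756, an ACF library labelled C57n:C3Hmt, was next in fibroblast (6.19) and macrophage (3.45) genes. The ACF comparisons are therefore given with and without library 489. Endothelial genes averaged 7.24 in library 489 and 5.44 to 7.28 in the others, so transcripts of other cells were present throughout set A. Which cells a changed transcript came from was not tested.

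The first question was how transcripts of the cardiomyocyte preparations differed 3 days after ACF, averaged over the 4 genotypes. Nppb, which encodes the precursor of the hormone BNP, rose by a log2 fold change of 1.23 (SE 0.205, edgeR adjusted p = 0.0149). It lay above the highest sham library of its labelled genotype in 10 of 12 ACF libraries. Its mean log2 CPM went from 6.51 ± 0.326 to 8.10 ± 0.744 in C3Hn:C3Hmt and from 6.33 ± 0.348 to 6.92 ± 1.04 in C57n:C57mt (SD, n = 3 each). In C57n:C57mt, Nppb was at 5.80 in ACF library 489 and at 7.09 and 7.86 in the others. The fitted difference was 0.78 (SE 0.406, edgeR adjusted p = 0.36) with library 489 and 1.17 (SE 0.355, adjusted p = 1) without it. In the libraries labelled C3Hn:C57mt it went from 6.01 ± 0.235 to 7.53 ± 0.307, and in those labelled C57n:C3Hmt from 6.68 ± 0.302 to 7.56 ± 0.626 (SD, n = 3 each). Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 0.97 (SE 0.139, edgeR adjusted p = 0.00971) and the secreted protease Adamts1 by 0.98 (SE 0.147). The endothelial early response gene Apold1 rose by 0.97 (SE 0.147). Spry4 and Dusp6, both feedback inhibitors of MAP kinase signalling, rose by 0.77 (SE 0.132) and 0.72 (SE 0.131). Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.33 (SE 0.274, edgeR adjusted p = 0.0439) and the secreted glycoprotein gene Lrg1 by 0.99 (SE 0.194). These rises were uneven. Mean log2 CPM of Cdkn1a went from 3.045 to 5.916 in C3Hn:C3Hmt and from 2.751 to 4.017 in C57n:C57mt. In those labelled C3Hn:C57mt and C57n:C3Hmt it went from 3.089 to 3.327 and from 4.135 to 4.609 (n = 3 each). For Lrg1 the changes were 3.058 to 4.717, 3.326 to 4.399, 3.154 to 3.7 and 3.517 to 3.826 in the same order. Csrnp1 rose by 0.87 (SE 0.153), the adhesion scaffold gene Nedd9 by 0.59 (SE 0.111) and Pfkp, a phosphofructokinase of glycolysis, by 0.59 (SE 0.122). Iigp1, an interferon-inducible GTPase gene, fell by 1.26 (SE 0.218, edgeR adjusted p = 0.0175). Angpt1, which encodes a ligand of the endothelial receptor Tek, fell by 0.90 (SE 0.162) and Ctage5 fell by 0.28 (SE 0.0547).

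In all, 37 of 13440 genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (27 higher, 10 lower; 1524 at an unadjusted p below 0.05). Of the 37, 36 had the same sign in each labelled genotype. Without library 489, 125 genes passed (82 higher, 43 lower), including all 37. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, had 2.42 (SE 0.5, edgeR adjusted p = 0.0439) with library 489 and 1.52 (SE 0.284, adjusted p = 0.0146) without it. Myh7, the slow myosin heavy chain gene, had 1.5 (SE 0.349, adjusted p = 0.0758) with it and rose by 1.62 (SE 0.29, adjusted p = 0.0122) without it. Without library 489, the phosphatase gene Ptprf rose by 0.72 (SE 0.16) and the kinase gene Mapk4 by 0.68 (SE 0.136). Scn4b, a sodium channel subunit gene, fell by 0.52 (SE 0.0964) and Phkg1, the catalytic subunit gene of muscle phosphorylase kinase, fell by 0.44 (SE 0.0776). The iron exporter gene Slc40a1 fell by 0.62 (SE 0.145) and the heat shock gene Hsph1 fell by 0.52 (SE 0.123). In the 24 libraries, Nppa (1.19, SE 0.297, edgeR adjusted p = 0.0948), Acta1 (0.35, SE 0.328, 0.756), Myh6 (-0.02, SE 0.237, 0.989) and the mitochondrial Cytb (0.02, SE 0.207, 0.993) did not pass. Nppa passed with DESeq2 (1.19, adjusted p = 0.00815), and in edgeR without library 465 (1.27, adjusted p = 0.0372), without 6756 (1.29, 0.0439) and with the set B libraries added as sham (0.90, 0.00477). With DESeq2, 236 genes passed, and with the set B libraries added as sham 6045 did. Adding the set B libraries mixes surgery with set, and in the exchanged labels with the nuclear profile, so these values do not single out ACF. Apold1 (0.27, SE 0.207, adjusted p = 0.298) did not pass with the set B libraries added, nor did Pfkp (0.0761) and Ctage5 (0.0879) without a filter on low counts. Leaving out 1 library at a time gave 12 to 174 genes, with 174 without 465, 56 without 490, 12 without 467, 14 without 6659, 15 without 6650, 483, 6692 or 464, 16 without 482, 17 without 6649, 18 without 6662 or 6661, 19 without 6652 or 6658, 21 without 6695 and 22 without 485. Thbs1 lost its call in 20 of these fits, Pfkp in 19, Cdkn1a, Lrg1 and Ctage5 in 16 each, Nedd9 in 9, Dusp6 and Angpt1 in 6 each and Csrnp1 in 1. In the fits that lost the call the log2 fold changes were 2.12 to 2.55 for Thbs1, 0.53 to 0.62 for Pfkp, 1.10 to 1.39 for Cdkn1a and 0.57 to 0.60 for Nedd9.

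**Figure D2:**
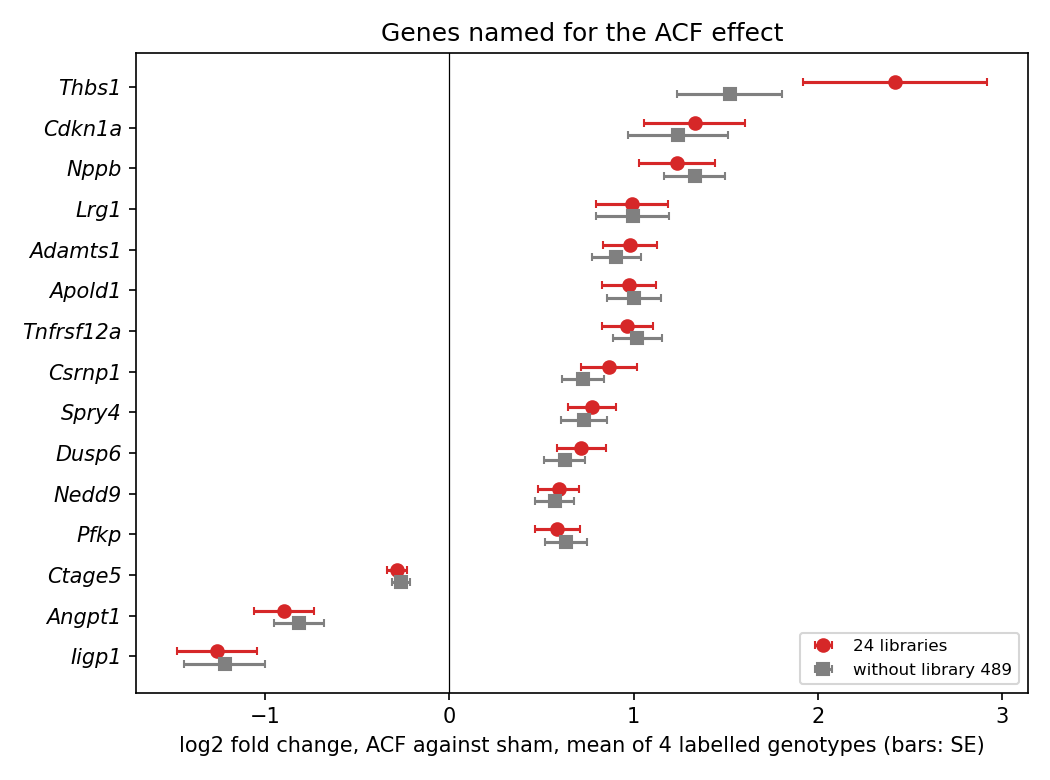
Log2 fold change (ACF minus sham, mean of the 4 labelled genotypes) of named genes, with all 24 set A libraries (red) and without library 489 (grey); bars are SE. Nppb had 1.23 and 1.33, and Thbs1 moved from 2.42 to 1.52.

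**Figure D3:**
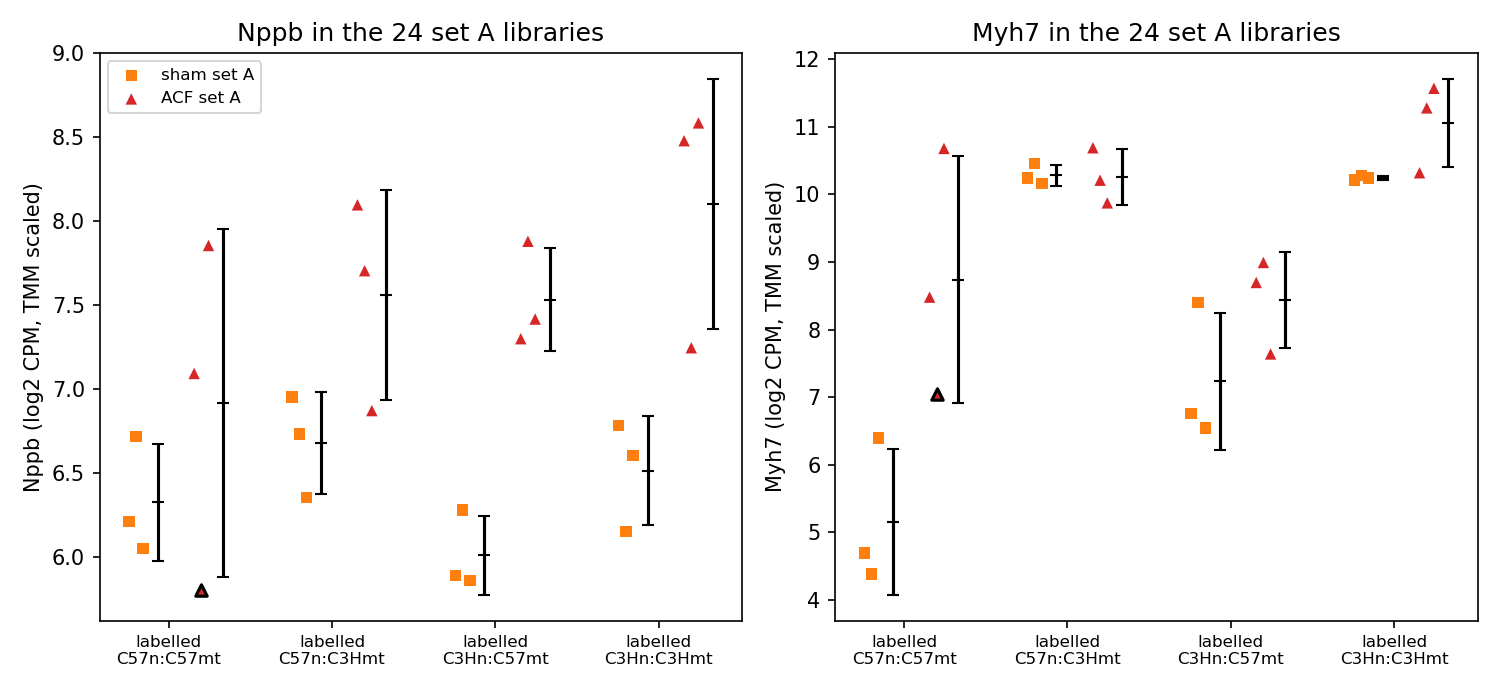
Log2 CPM of Nppb and Myh7 per library in the 4 labelled genotypes of set A, sham and ACF; each point is 1 library, bars are the mean ± SD of 3 libraries, and library 489 has a black outline. Mean Nppb was higher after ACF in each labelled genotype, from 6.51 to 8.10 in C3Hn:C3Hmt and from 6.33 to 6.92 in C57n:C57mt, where library 489 was at 5.80.

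Of the gene lists, the cytoskeleton and intercalated disc genes rose as a group after ACF (camera adjusted p = 6.28e-05, adjusted p = 0.029 with an estimated correlation). Of its 27 measured members, 1 was higher over all genes tested, the nuclear lamina gene Lmna, and 5 were higher and 0 lower adjusted over the list alone. Without library 489 the call with an estimated correlation ended (adjusted p = 0.105). The cardiac stress and fetal genes were higher by camera (24 members, adjusted p = 7.84e-08, adjusted p = 0.243 with an estimated correlation). In it 1 member, Nppb, was higher over all genes and 6 higher adjusted over the list alone (10 without library 489). Immediate early and dissociation stress genes were higher by camera (26 members, adjusted p = 1.6e-11, adjusted p = 0.312 with an estimated correlation). The transcription factor gene Maff led them at 1.00 (SE 0.202, edgeR adjusted p = 0.0415), and 15 members were higher and 1 lower adjusted over the list alone. Sham and ACF cells were both isolated with collagenase, and whether isolation had a part in this rise was not tested. Inflammatory mediator genes were higher by camera (25 members, adjusted p = 1.6e-11, adjusted p = 0.56 with an estimated correlation). Lcn2, which encodes an iron-binding acute phase protein, was at 2.71 (SE 0.511, edgeR adjusted p = 0.0273), and 11 members were higher adjusted over the list alone. Library 489, which had the highest neutrophil and macrophage means, moved these values. Without it the list's median difference went from 0.86 to 0.36 (camera adjusted p = 1.13e-05, adjusted p = 0.644 with an estimated correlation). Lcn2 was then at 2.33 (SE 0.461, edgeR adjusted p = 0.0187), and 5 members were higher adjusted over the list alone. Extracellular matrix genes were higher by camera (37 members, median 0.44, adjusted p = 1.08e-07, adjusted p = 0.722 with an estimated correlation), with a median of 0.16 without library 489 (camera adjusted p = 0.00219, adjusted p = 0.974 with an estimated correlation). Thbs1 passed the test, and Tnc, the tenascin C gene, had 2.62 (SE 0.596, edgeR adjusted p = 0.0695) and 1.65 (SE 0.364, adjusted p = 0.0335) without library 489. Macrophage and erythrocyte genes were also higher by camera (adjusted p = 0.00751 and 0.0078, adjusted p = 0.915 and 0.722 with an estimated correlation). Without library 489 neither was (camera adjusted p = 0.933 and 0.909). Respiratory complex I genes were lower by camera (36 members, 0 past the test, adjusted p = 0.0243, adjusted p = 0.915 with an estimated correlation). Without library 489 they were not called (camera adjusted p = 0.532). Glycolysis genes passed camera without library 489 (25 members, adjusted p = 7e-07, adjusted p = 0.644 with an estimated correlation). Pfkp was then at 0.63 (SE 0.114, edgeR adjusted p = 0.0127) and the hexokinase gene Hk1 at 0.44 (SE 0.084, adjusted p = 0.0147).

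Within single genotypes, fewer genes passed. In the libraries labelled C57n:C3Hmt, Spry4 rose by 1.79 (SE 0.266, edgeR adjusted p = 0.0235) and was the single gene called. No gene passed in C57n:C57mt, in C3Hn:C3Hmt or in the libraries labelled C3Hn:C57mt. The counts at an unadjusted p below 0.05 in edgeR were 2030 in C57n:C57mt, 951 in C3Hn:C3Hmt, 274 in those labelled C3Hn:C57mt and 230 in those labelled C57n:C3Hmt. Without library 489 they were 551, 1755, 542 and 729 in the same order, so C57n:C57mt no longer had the highest count. DESeq2, with library 489 included, called 146, 76, 1 and 3 genes in that order. Without library 489, whose exclusion also changes the shared spread, Myh7 rose by 4.52 (SE 0.666, edgeR adjusted p = 0.019) in C57n:C57mt as the single gene called. In C3Hn:C3Hmt 69 genes then passed (28 higher, 41 lower). Cdkn1a rose by 3.16 (SE 0.54, edgeR adjusted p = 0.0222), Fkbp5, a glucocorticoid-induced gene, by 2.71. Nppb rose by 1.67 (SE 0.33, adjusted p = 0.0306) and Lrg1 by 1.89. Iigp1 fell by 2.25 (SE 0.434, adjusted p = 0.0278), and Spna1, an erythroid spectrin gene, fell by 2.59 (SE 0.344, adjusted p = 0.00419). The erythrocyte genes of these C3Hn:C3Hmt libraries averaged 1.96 ± 0.639 in sham and 0.76 ± 0.761 in ACF, and Alas2 had 2.58 ± 0.639 and 0.68 ± 0.785 (log2 CPM, SD, n = 3 each). The clock output gene Dbp fell by 1.59 (SE 0.335, adjusted p = 0.0404). Leaving out single libraries gave 874 genes in C57n:C57mt without library 465, 688 without 490 and 1 without sham library 491 (Gm16119, chosen after its value was seen). These fits kept library 489, without which 1 gene passed there. In C3Hn:C3Hmt, leaving out single libraries gave 5 without 471 (Cdkn1a, Lrg1, Fam168a, Gadd45a and C530008M17Rik) and 2 without sham library 485 (Iigp1 and Spna1). Spry4 lost its call without 6650, 6662, 6649, 6652 or 6661 (0 genes each) and in a fit of its own 6 libraries (edgeR adjusted p = 0.161). Simulated changes in 3 against 3 libraries of C57n:C57mt were recovered for 13.4% of genes changed 1.5-fold, 47.8% at 2-fold and 98.5% at 4-fold.

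The next question was whether the response to ACF depended on the mitochondrial or the nuclear background. For Myh7 the response differed by -4.0 (SE 1, edgeR adjusted p = 0.992) between the libraries labelled C57n:C3Hmt and those of C57n:C57mt, which did not pass. These groups carried opposite nuclear profiles, so the difference cannot be assigned to the mitochondria. No gene passed in edgeR for the mitochondrial difference on the labelled C57 nucleus (402 at an unadjusted p below 0.05, and 0 in DESeq2), for that on the labelled C3H nucleus (351, and 1 in DESeq2) or for the nuclear difference (920, and 0 in DESeq2). Without library 489 the edgeR counts were again 0 (549, 734 and 411 at an unadjusted p below 0.05). Because the exchanged libraries carry the other strain's nuclear profile, both labelled mitochondrial differences also hold the nuclear one. Each side of the labelled nuclear difference averaged groups of both profiles, so its count of 0 does not test the nucleus. Reading the title prefix as the nuclear background gave 0 for each with all 24 libraries, and without library 489 it gave 1 gene for the nuclear difference (Spna1, named after its value was seen, -2.04, SE 0.282, edgeR adjusted p = 0.00751). Camera called 16, 6 and 23 of 32 gene lists in these comparisons (17, 10 and 21 of 33 without library 489), and 0 were called with an estimated correlation or by fry. In simulated data, 1.49% of 1.5-fold, 11.9% of 2-fold and 71.2% of 4-fold differences in response to ACF by mitochondria on the labelled C57 nucleus were recovered, so a 2-fold difference there was mostly not detectable with 3 libraries per group. The other differences in response were not simulated.

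In sham libraries, the mitochondrial exchange was compared on a fixed nuclear background, and the values are from set B, where the genes chosen on unexchanged libraries matched the nuclear labels of the exchanged ones. Prkcq, the protein kinase C theta gene, was lower with C3H than with C57 mitochondria on the C3H nucleus, by a log2 fold change of -0.98 (SE 0.142, edgeR adjusted p = 0.00433). Its mean log2 CPM was 2.14 ± 0.393 and 3.15 ± 0.146 (SD, n = 6 each). It was the single gene called on that nucleus (1257 at an unadjusted p below 0.05). The sham libraries of set A did not show this order, with Prkcq at 2.56 ± 0.0132 in C3Hn:C3Hmt, 2.07 ± 0.074 in those labelled C3Hn:C57mt and 2.39 ± 0.145 in those labelled C57n:C3Hmt, which carry the C3H profile (SD, n = 3 each). Over both sets, where the exchanged label pools both nuclear profiles, the difference was -0.53 (SE 0.16, edgeR adjusted p = 0.716). On the C57 nucleus 0 of 13395 genes passed in edgeR (1509 at an unadjusted p below 0.05). The mitochondrial transcripts Cytb (0.97, SE 0.303, edgeR adjusted p = 0.27), Cox2 (0.85, SE 0.293, 0.305) and Atpase6 (0.95, SE 0.32, 0.3) had higher values with C3H mitochondria on the C57 nucleus and did not pass. For the mean over both nuclei and for the interaction 0 genes passed (549 and 2188 at an unadjusted p below 0.05). Leaving out single libraries gave 422 genes for the interaction without replicate 5 of C57n:C57mt, 9 without 19, 6 without 20 or 2, 3 without 22 (Igf1, Dpep1 and Cxcl14), 2 without 13 (Igf1 and Dpep1) and 1 without 3 (AK161748). On the C57 nucleus it gave 2 without 7 (Cd48 and Dpp6) and 1 without 8 (4930523C07Rik), which was also the 1 gene over both nuclei, all named after their values were seen. In simulated set B data, 71.6% of 1.5-fold and 95.5% of 2-fold changes on the C57 nucleus were recovered. The simulation held no differences shared by many genes of a library and none by L code. The shares may therefore be too high for the real libraries, and 2-fold differences are not ruled out.

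The L code of the titles varied with the genotype in set B. All 6 C57n:C57mt libraries carried L8 and all 6 C3Hn:C3Hmt libraries L3, while C57n:C3Hmt had 4 with L2 and 2 with L8, and C3Hn:C57mt had 4 with L2 and 2 with L3. Within C57n:C3Hmt, Cytb was at 16.34 to 16.55 log2 CPM in the 2 libraries with L8 and at 15.52 to 15.61 in the 4 with L2. Within C3Hn:C57mt it was at 14.16 to 14.68 in the 2 with L3, inside the 13.93 to 15.84 of the 4 with L2. The mitochondrial comparison within 1 L code therefore rests on 2 exchanged libraries per nucleus. With the L code as a covariate in set B, Cytb had 1.52 (SE 0.364, edgeR adjusted p = 0.333), Cox2 1.44 (SE 0.335, 0.322) and Atpase6 1.59 (SE 0.365, 0.322) on the C57 nucleus, where 0 genes passed (641 at an unadjusted p below 0.05). On the C3H nucleus 30 genes then passed (9 higher, 21 lower with C3H mitochondria), Prkcq among them at -1.10 (SE 0.191, adjusted p = 0.0095). The mitochondrial uncoupling protein gene Ucp3 was lower at -1.95 (SE 0.293, adjusted p = 0.0022), as were Angptl4, which encodes an inhibitor of lipoprotein lipase, at -2.11 (SE 0.29) and Klhl38 at -1.84 (SE 0.205). Over both nuclei 3 genes passed (Angptl4, Ucp3 and Siah2), and for the interaction 2 did (Klhl38 and Frat2). The genes of this fit were named after their values were seen.

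Several gene groups of set B, without the L code as a covariate, had members on one side on 1 or both nuclei. On the C57 nucleus, 0 of 15 macrophage genes had a positive difference, C3H minus C57 mitochondria (median -0.70, camera adjusted p = 1.18e-08, adjusted p = 0.482 with an estimated correlation). Of these 5 were lower adjusted over the list alone, among them Cd14 at -1.14, the lysozyme gene Lyz2 at -0.87 and the receptor gene Csf1r at -0.69. Interferon response genes had 0 of 28 positive differences (median -0.47, camera adjusted p = 1.43e-09, adjusted p = 0.482 with an estimated correlation). Of these 4 were lower adjusted over the list alone, among them the antiviral genes Oas1a at -0.98 and Oasl2 at -0.79. Fibroblast genes had 1 of 12 positive (median -0.45, camera adjusted p = 1.2e-05, adjusted p = 0.482 with an estimated correlation). Of these 3 were lower adjusted over the list alone. Extracellular matrix genes had 2 of 36 positive (median -0.39, camera adjusted p = 1.02e-07, adjusted p = 0.482 with an estimated correlation). Genes of the TCA cycle had 11 of 21 positive there (median 0.02, camera adjusted p = 0.924). Adult sarcomere genes had 19 of 22 (median 0.12, camera adjusted p = 0.00358, adjusted p = 0.482 with an estimated correlation, and camera adjusted p = 0.812 with the L code as a covariate). On the C3H nucleus, fibroblast genes had 12 of 12 positive differences (median 0.56, camera adjusted p = 1.35e-09, adjusted p = 0.414 with an estimated correlation). Of these 9 were higher adjusted over the list alone, among them the collagen genes Col3a1 at 0.93 and Col1a1 at 0.84. Extracellular matrix genes had 35 of 36 positive (median 0.50, camera adjusted p = 1.11e-14, adjusted p = 0.414 with an estimated correlation), and 16 were higher adjusted over the list alone. Macrophage genes had 14 of 15 (camera adjusted p = 1.79e-06, adjusted p = 0.414 with an estimated correlation). Genes of the TCA cycle had 0 of 21 positive (median -0.21, camera adjusted p = 4.87e-09, adjusted p = 0.414 with an estimated correlation). Adult sarcomere genes had 1 of 22 (camera adjusted p = 6.55e-07, adjusted p = 0.414 with an estimated correlation). Interferon response genes had 19 of 28 positive on that nucleus (median 0.16, camera adjusted p = 0.129), and 14 of 28 with the L code as a covariate (median -0.04). No single member of these lists passed over all genes tested. The difference between the nuclei was itself called by camera for the extracellular matrix, macrophage and fibroblast genes (adjusted p = 4.66e-16, 5.23e-11 and 5.23e-11, adjusted p = 0.303, 0.299 and 0.299 with an estimated correlation).

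The counts adjusted over the list alone depended on single libraries of set B. On the C57 nucleus the macrophage count fell to 0 without replicate 1 of C57n:C57mt or 10 of C57n:C3Hmt, the fibroblast count without 1, 2 or 10, and the interferon response count without 1, 2, 9, 10 or 11. On the C3H nucleus the fibroblast count fell to 0 without replicate 17 of C3Hn:C57mt or 23 of C3Hn:C3Hmt, the extracellular matrix count without 14, 17, 18 or 23, and the macrophage count without 23. Over the 24 fits the counts were 0 to 9 (macrophage), 0 to 6 (fibroblast) and 0 to 9 (interferon response) lower on the C57 nucleus. On the C3H nucleus they were 0 to 12 (fibroblast), 0 to 22 (extracellular matrix) and 0 to 8 (macrophage) higher. Replicate 23 of C3Hn:C3Hmt stood apart in its group, with fibroblast genes at 5.48 against 3.88 to 4.44, macrophage genes at 2.66 against 1.11 to 1.75 and the lowest cardiomyocyte mean (11.48). Without it the medians on the C3H nucleus were 0.29 for fibroblast, 0.26 for extracellular matrix and 0.28 for macrophage genes (from 0.62), and -0.14 for TCA cycle genes. Camera still called all 4 (adjusted p = 7e-07, 3.31e-08, 0.00052 and 2.3e-05, adjusted p = 0.597, 0.597, 0.698 and 0.698 with an estimated correlation), and 0 members of each were called adjusted over the list alone. On the C57 nucleus the macrophage median was -0.44 without replicate 1 of C57n:C57mt. The adult sarcomere median there was 0.07 without replicate 3 of C57n:C57mt, and camera called that list in 23 of the 24 fits. For interferon response genes on the C3H nucleus the median ran from -0.06 to 0.34, with camera calls in 5 of the 24 fits. Replicate 10 of C57n:C3Hmt was also far from its group in fibroblast genes, at 3.41. With the L code as a covariate the medians on the C57 nucleus were -0.65 (macrophage), -0.26 (interferon response) and -0.34 (fibroblast), with 0 members called adjusted over each list alone. On the C3H nucleus they were 0.92 (fibroblast), 0.97 (extracellular matrix), 0.40 (macrophage), -0.35 (TCA cycle) and -0.29 (adult sarcomere). Adjusted over each list alone, 10 fibroblast and 26 extracellular matrix genes were higher there and 2 adult sarcomere genes lower. For macrophage and TCA cycle genes 0 members were called. Camera called the lists behind all 8 medians (adjusted p of 3.25e-15 to 0.0288), and with an estimated correlation 0 were (adjusted p of 0.491 to 0.874).

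Over the 36 sham libraries of both sets, with the set as a term, 0 of 13276 genes passed in edgeR for the mitochondria on the C57 nucleus, on the C3H nucleus, over both, or for their interaction (1254, 763, 1581 and 542 at an unadjusted p below 0.05, and 43, 15, 30 and 7 in DESeq2). In this fit each exchanged label pools libraries of both nuclear profiles, so these counts do not test the mitochondria. Within set A as labelled, 861, 1129, 1939 and 0 genes passed. The exchanged libraries of set A carry the nuclear profile of the other strain, so the first 3 counts hold the nuclear difference. With the title prefix read as the nuclear background, the comparison over both nuclei becomes the nuclear comparison within set A. Its 1939 genes are therefore the same result as that given below for the title prefix. Across 14041 genes, which are not independent replicates, the mitochondrial log2 fold changes on the C57 and the C3H nucleus had r = 0.505 (Spearman rho 0.286) in both sets together, 0.789 (0.578) in set A and -0.372 (-0.292) in set B. Values as far from 0 occurred in 3, 4 and 1 of 100 random relabellings, and the pooled relation therefore did not hold within set B. In set A the relabelled values reached -0.789 and 0.789, so those as far from 0 may be the real split or its mirror. In set B only exchanged genotypes carried L2, and they enter the 2 differences with opposite signs. A difference by L code could therefore also give a negative r there, and the 2 sources cannot be told apart. With the genes called for the nuclear background left out, r was 0.175 over both sets (35 of 100 relabellings as far from 0), 0.514 in set A (1 of 100) and -0.39 in set B (2 of 100). The genes left out were the 2491 called over both sets as labelled, against 4776 called in set B alone. Genes of the nuclear difference may therefore have stayed in, and the 0.514 in set A is not freed of it. With the title prefix read as the nuclear background r was -0.0658 over both sets (70 of 100) and 0.185 in set A (42 of 100). Under that reading the effects in set A and set B had r = -0.387 on the C57 nucleus (1 of 100) and 0.1 on the C3H nucleus (49 of 100), and as labelled 0.0647 (55 of 100) and -0.226 (15 of 100).

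The nuclear background was compared in sham libraries as a scale for the mitochondrial effect. In set B, Myh7 was higher in C3Hn than in C57n by a log2 fold change of 5.00 (SE 0.157, edgeR adjusted p = 4.01e-19). Its counts were 33099 to 61344 per library against 624 to 2725. The skeletal muscle light chain gene Myl1 was higher by 3.35 (SE 0.12) and Acta1, skeletal actin, by 2.17 (SE 0.221, edgeR adjusted p = 1.06e-08). Nppa, the atrial natriuretic peptide gene, was higher by 1.37 (SE 0.222, adjusted p = 1.98e-05), while Nppb had 0.09 (SE 0.152, adjusted p = 0.699). Kcnj14 was higher by 6.03 (SE 0.103, edgeR adjusted p = 2.36e-24) and the orphan receptor gene Gpr179 by 7.80 (SE 0.258). Iqgap2 was higher by 4.98 (SE 0.128) and the formin gene Fmn1 by 4.92 (SE 0.106). The securin gene Pttg1 was lower in C3Hn, at -4.51 (SE 0.124), as was Sorcs2 at -4.53 (SE 0.191). Also lower were Cyfip2 at -2.99 (SE 0.101), the cytokine gene Il15 at -2.43 (SE 0.0856) and the class II histocompatibility genes H2-Eb1 at -2.76 and H2-Aa at -2.37. The mitochondrial Cytb was lower by edgeR, at -0.56 (SE 0.213, adjusted p = 0.0428). It did not pass with DESeq2 (adjusted p = 0.0616) or in 14 of the 24 edgeR fits that left out 1 library, and had 0.38 (SE 0.437, adjusted p = 0.652) with the L code of the titles as a covariate.

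In set B 4776 of 13395 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (2525 higher and 2251 lower in C3Hn), and 1399 did with the L code as a covariate (797 higher, 602 lower). Of the 24 measured cardiac stress and fetal genes, 16 were higher and 1 lower over all genes, and 17 and 1 adjusted over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.0852 with an estimated correlation). Nmrk2 was higher by 2.31 (SE 0.201) and Fhl1 by 1.00 (SE 0.0692). Of the 20 ER stress genes, 16 were lower over all genes and 17 adjusted over the list alone (camera adjusted p = 0.00045, adjusted p = 0.996 with an estimated correlation). Among them were the protein disulfide isomerase gene Pdia6 at -0.64, the transcription factor gene Xbp1 at -0.54 and the chaperone gene Calr at -0.49. Over both sets, where each exchanged label pools both nuclear profiles, 2491 of 13276 genes passed (1249 higher, 1242 lower). Gpr179 was at 5.14 (SE 0.765, edgeR adjusted p = 2.28e-05), Fmn1 at 3.30, Pttg1 at -3.19 and Emilin2 at -1.70. Within set A as labelled 1 gene passed, the zinc finger gene Zfp709 at -1.04 (SE 0.125, edgeR adjusted p = 0.0182), named after its value was seen. There Gpr179 had 1.10 (adjusted p = 0.6) and Pttg1 -0.27 (adjusted p = 0.702). With the title prefix of the set A libraries read as the nuclear background, 5524 genes passed over both sets and 1939 within set A. Within set A this is the same test as the labelled mitochondrial one over both nuclei, so the 1939 are no separate result. The submitters' processing notes name mm9, a C57BL/6J genome build, and how well reads of C3H alleles mapped was not measured here.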

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

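All tests of explanations in this part were chosen after the results were seen, while the counts over other groupings of the libraries and the search for single libraries far from their group were planned.

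As labelled, the sham comparisons differed between set A and set B for 798 genes (mitochondria on the C57 nucleus), 1502 genes (mitochondria on the C3H nucleus) and 3059 genes (nuclear background), by an edgeR term for the difference. With the title prefix of the set A libraries read as the nuclear background, the counts were 1, 3 and 11. The 1 gene was Inmt (3.92, SE 0.529, edgeR adjusted p = 0.000212), the 3 were Zfp709 (-1.71, SE 0.183), Zdhhc2 (-1.51, SE 0.268) and AK030561 (-1.14, SE 0.21), all given as set A minus set B and chosen after their values were seen.

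The first pattern weighed was the nuclear profile of the exchanged libraries of set A. All 12 had a strain score on the side opposite to the labelled nucleus, which is the pattern itself and no test of a wrong genotype label. None of the 12 (0) scored between 0.2 and 0.8, which argues against mixed RNA of both strains, and 0 of the 12 unexchanged set A libraries scored on the wrong side, which argues against a difference between the sets as such. With genes chosen on the unexchanged set B libraries alone, 0 of the 12 exchanged set B libraries scored on the side opposite to the labelled nucleus, which argues against the mitochondrial genome setting these genes. A genotype tag of set A that swaps the nuclear and mitochondrial parts of both exchanged groups is a candidate explanation that stays open, since the mitochondrial genome was not tested.

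The second pattern was library 489, an ACF library of C57n:C57mt. It had the highest mean of the 24 set A libraries in 5 of the 6 lists of blood and other cells. These levels set the library apart in the first place, so they do not test RNA from blood and other cells in that preparation, which stays open. Its strain scores of -0.00739 (genes higher in C3Hn) and 0.28 (genes higher in C57n) lay below those of the libraries with a C3H profile (at least 0.866 and 0.892), which argues against a library of the other strain, while the 0.28 lay above the other libraries with a C57 profile (at most 0.0807) and was not explained. Its total of 20.66 M counts lay within the range of the others, which argues against library size, and of the other 11 ACF libraries 1 had an erythrocyte mean above the highest sham library, which argues against a response shared by the ACF animals. Whether the cells entered at isolation or were more abundant in that heart was not tested.

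In groups of 6, single libraries lay far from the rest in 4 of 84 pairs of group and measure, where chance gives about 1 in 20. They were the fibroblast mean of C3Hn:C3Hmt set B replicate 23 (5.478, the others 3.875 to 4.44), the fibroblast mean of C57n:C3Hmt set B replicate 10 (3.414, the others 3.915 to 4.167), the atrial cardiomyocyte mean of C3Hn:C3Hmt replicate 19 (3.451, the others 1.792 to 2.263) and the adipocyte mean of C57n:C3Hmt replicate 7 (-0.3791, the others -3.396 to -2.404).

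For the mean ACF effect, 1 of 50 groupings of the same libraries, the real one, gave 37 genes or more and the highest other gave 0. This argues against a chance assignment of libraries to groups. It does not exclude one, since a share of 0.02 is the smallest that 50 groupings can give. For the nuclear background the real 2491 was again 1 of 50 with 0 as the highest other. For the ACF effect in single genotypes there are 10 groupings, too few for a share under 0.05: the real counts were 0, 1, 0 and 0 in C57n:C57mt, those labelled C57n:C3Hmt, those labelled C3Hn:C57mt and C3Hn:C3Hmt. The highest others were 0, and 10, 1, 10 and 10 groupings gave as many. For the comparisons with a real count of 0, every grouping must give as many (50 of 50), so the groupings say nothing about chance there. The highest others were 440 (ACF effect by mitochondria, labelled C57 nucleus), 0 (labelled C3H nucleus), 0 (by nuclear background), 1869 (sham mitochondria on the C57 nucleus), 0 (on the C3H nucleus), 2 (over both) and 0 (interaction). Which libraries the groupings with 440 and 1869 genes put together was not examined, so their source is not known.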

How the results depend on the processing

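Fits by title prefix, without libraries 489 and 6756 and under other settings within set B alone were chosen after seeing the data, and the others were planned. Among counts of genes, list calls and correlations, 273 values under the alternatives equalled or stayed within 1.5 times the reported one and 65 moved further. Counts of 0 that stayed at 0 are among the 273. Since the reported count was 0 in most comparisons, this total does not measure how stable the other counts were. Another 2 correlations changed sign. Of the named genes, 3175 values kept their direction and side of the threshold, 161 lost and 98 gained the call, and 2 changed sign. The cause was not tested for any change unless given. DESeq2 called 146, 3, 1 and 76 genes for the ACF effect in C57n:C57mt, C57n:C3Hmt, C3Hn:C57mt and C3Hn:C3Hmt as labelled, 236 for their mean, 1 for the mitochondrial difference in response on the labelled C3H nucleus, and 43, 15, 30 and 7 for the sham mitochondrial comparisons and their interaction. The 3 were Spry4, Adamts1 and Apold1, and the single genes were AK172683 for those labelled C3Hn:C57mt and Scgb1a1 for the difference in response. The log2 fold changes of these single genes were 18.29 (SE 3.48) and 23.4 (SE 4.79). Neither was called by edgeR, and their counts were not examined, so these sizes should not be relied on. The sham counts of 43, 15, 30 and 7 come from libraries that pool both nuclear profiles under each exchanged label. With all 48 libraries, so that set and surgery are mixed, the ACF counts were 2673, 203, 454 and 302, 6045 for the mean, 41 for the mitochondrial difference on the C57 nucleus and 72 for the nuclear one. For the exchanged labels the nuclear profile is mixed in as well. In a fit of the compared libraries only, those labelled C57n:C3Hmt gave 0. Without libraries 489 and 6756 the counts were 1 (Myh7), 2 (Spry4 and Spna1), 192 in C3Hn:C3Hmt, 344 for the mean and 1 (Spna1) for the mitochondrial difference on the labelled C3H nucleus. Set A alone as labelled gave 861, 1129 and 1939 genes for the sham mitochondrial comparisons and 1 for the nuclear one, where Acta1 turned to -0.543. Set B alone gave 1 (mitochondria, C3H nucleus) and 4776 (nuclear), where Cytb turned to 0.376 with the L code as a covariate. Title prefixes gave 5524 genes for the nuclear comparison, and in set A alone 3 (Bpifb4, Zdhhc2 and Zfp709) and 1 (Zfp709) for the mitochondria on the C3H nucleus and over both. The last of these is the same test as the labelled nuclear one in set A. Of 411 list tests, 152 were called by camera at the preset correlation, 1 with an estimated correlation and 3 by fry. The correlation of mitochondrial effects, 0.505, became 0.789 in set A, -0.372 in set B, 0.175 without nuclear calls and -0.0658 by title prefix.

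Leaving out each library of the groups compared, in the fits of 24 ACF and sham or 36 sham libraries, gave 0 to 874 genes for the ACF effect in C57n:C57mt, 0 to 1 in those labelled C57n:C3Hmt, 0 to 0 in those labelled C3Hn:C57mt, 0 to 5 in C3Hn:C3Hmt (69 without library 489 of another group), 12 to 174 for the mean, 0 to 1 for the sham mitochondria on the C57 nucleus (6030419C18Rik, without set B replicate 5 of C57n:C57mt) and 2177 to 3165 for the nuclear comparison. The other counts stayed at 0 in these edgeR fits. Within set B alone the counts were 0 to 2 (mitochondria, C57 nucleus), 1 (C3H nucleus), 0 to 1 (over both), 0 to 422 (interaction) and 4456 to 5266 (nuclear). No paired analysis was possible because no replicate number was shared between groups. A covariate for sex was not run because no library differed in sex genes. The number of libraries limits these counts, and not only for changes under 2-fold. In simulated data, 47.8% of 2-fold changes were recovered in 3 against 3 libraries of C57n:C57mt. For the difference in response by mitochondria on the labelled C57 nucleus, 11.9% at 2-fold and 71.2% at 4-fold were recovered. How depth limits genes with few counts was not tested.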

Other observations

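Interferon response genes were not described above for ACF. Without library 489, 1 of 28 measured members had a positive mean difference, ACF minus sham (median -0.44, camera adjusted p = 8.57e-09, adjusted p = 0.845 with an estimated correlation), and 0 members passed over all genes, while Iigp1, an interferon-inducible GTPase gene outside the list, fell by 1.26 (SE 0.218) in the 24 libraries. With library 489 the list's median was -0.26 (camera adjusted p = 0.00516, adjusted p = 0.915 with an estimated correlation). Cell cycle genes had 22 of 23 positive differences with library 489 (median 0.76, camera adjusted p = 5.64e-07, adjusted p = 0.722 with an estimated correlation), 6 higher and 1 lower adjusted over the list alone, and 20 of 23 without it (median 0.33, camera adjusted p = 0.00597, adjusted p = 0.949 with an estimated correlation), with 0 higher and 1 lower adjusted over the list alone. Adult sarcomere genes had 19 of 22 positive differences without library 489 (median 0.11, camera adjusted p = 0.00059, adjusted p = 0.949 with an estimated correlation).

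The third pattern weighed was Myh7 after ACF by the strain that opens the titles, a test chosen after the values were seen. With a C57 title prefix Myh7 had a mean log2 CPM of 6.19 ± 1.47 in sham and 8.59 ± 1.25 in ACF libraries, and with a C3H prefix 10.26 ± 0.103 and 10.66 ± 0.656 (SD, n = 6 each). The difference in response was -2.07 (SE 0.691, edgeR adjusted p = 1), and -2.34 (SE 0.575, adjusted p = 0.65) without library 489, so a dependence of the Myh7 response on the nuclear background may exist and stayed undecided. Of the 6 ACF libraries with a C3H prefix, 3 lay above the highest sham library by more than the SD, which argues against a ceiling of Myh7 there, and the difference was -1.58 (SE 0.546) without libraries 489 and 490, which argues against library 490 as its only source. In the fit without library 489 the single gene called for this difference was Spna1 (-2.04, SE 0.282, edgeR adjusted p = 0.00751), named after its value was seen. The erythrocyte means were 1.10 ± 1.3 in sham and 0.67 ± 1.28 in ACF libraries with a C3H prefix (SD, n = 6 each), and 0.40 ± 1.6 (n = 6) and 1.08 ± 2.13 (n = 5) with a C57 prefix.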
